A study of Mus musculus with 11 samples.

How the data were processed

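The libraries are V(D)J-HTGTS libraries (also called VDJ-seq) of the mouse immunoglobulin heavy chain locus, Igh. Genomic DNA came from bone marrow pro-B cells sorted as CD19 and CD43 positive, per the labels' protocols. Sonicated DNA was copied by linear amplification-mediated PCR from a biotinylated primer at the JH1 or the JH4 segment (the bait), captured on streptavidin beads, ligated to adapters and amplified by nested PCR, per the labels' protocols. The protocol names no molecular identifiers, so several reads of a junction can be PCR copies of 1 molecule. The amount of DNA taken differed between libraries within a stated range, per the labels' protocols, so read numbers are not normalised to cells.

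The authors deposited 1 read table per library, with 1 row per read. Per the file headers, a row gives the read's VH, DH and JH segments, its V-J reading frame, the bases between segments, the CDR3 sequence and the number of aligned V bases. No column holds counts per gene, so reads were tallied here. Every row is marked as passed, has a VH call to 1 gene and has at least 100 aligned V bases. Rows with only DH joined to JH were not analysed here, so the planned share of complete VDJ joins was not computed. The submitters' processing notes name the genome build mm9. The aligner and the tool that called the segments are not given in the sources used here. Positions on the genome are not printed, because the gene table used here belongs to another assembly, GRCm38.p6. That table gave the order of the VH genes from the DH end of the locus, and 99.9% of reads carried a VH name that it holds.

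Groups were taken from the sample titles: control (Cfp1 flanked by loxP sites) and knockout (the same with Mb1-Cre, a recombinase driven by the B-lineage gene Cd79a), each at both baits. The titles number biological replicates. They do not say whether JH1 and JH4 libraries with the same number come from 1 animal, so p-values treat the 11 libraries as independent. The assay reads Igh only, so deletion of Cfp1 cannot be checked in these libraries. Read names showed 2 sequencing runs. The first held all JH1 libraries, JH4 control replicate 1 and JH4 knockout replicate 1, and the second held the other JH4 libraries.

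VH families were put into 3 domains before the data were examined. Distal families were IGHV1 and IGHV8. Proximal families, nearest to DH, were IGHV5 and IGHV2. Middle families were IGHV3, 4, 6, 7, 9, 10, 11, 12, 13 and 14. The families IGHV15 and IGHV16 entered the denominator only. DH shares and N nucleotides used reads with a DH call. A productive read was in frame without a stop codon. CDR3 length was averaged over in-frame reads. Bases that either neighbouring segment could have supplied were not counted as N nucleotides. A distinct junction was a unique combination of VH, DH and JH segments, their end bases and the bases between them.

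Each per-library value was compared with a 2-sided exact permutation test in which genotype labels were permuted within bait. Its statistic was the mean over both baits of the knockout mean minus the control mean. The 200 arrangements allow no p below 0.005, and the test within a single bait cannot go below 0.1. The 12 per-library measures formed 1 family for Benjamini-Hochberg adjustment, the 16 VH families another and the 12 DH segments the last. Whether the genotype difference differed between baits was tested by permuting bait labels within genotype. Distinct junctions per 100 drawn reads were averaged over 1000 draws, leaving out libraries with fewer than 100 reads. Intervals of single-library shares are 95% exact binomial intervals (Clopper-Pearson). A count of 0 allows up to 3 reads. Intervals and limits cover counting error only, since reads can be PCR copies.

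VH segments with at least 10 reads were tested with limma (voom weights, genotype and bait as terms, Benjamini-Hochberg adjustment). This fit was fixed before the data were examined. It was then tested on simulated data with the real numbers of reads and distinct junctions. In 20 simulations without any change, limma called on average 20.35 of 125.9 segments higher in knockout libraries, and 16.95 of those calls had no knockout read. The fixed offset that voom adds to each count is large against libraries of 58 to 962 reads. Quasi-binomial regression, named as an alternative beforehand, called on average 0.5 segments in the same simulations, and on distinct junctions it called 0. limma restricted to segments with a mean share of at least 2% also called 0. When 20 segments were changed 8-fold, the quasi-binomial fit recovered 20.0% of them, its form on distinct junctions 24.25%, and limma 27.5% at the cost of 29.2 false calls. The quasi-binomial fit of reads made 3.15 false calls on average, and 1.5 of its 4.35 lower calls were right. On distinct junctions it made 0 false calls. Single segments are therefore described from their shares and the quasi-binomial fits, with the limma values beside them. The permutation test gave p under 0.05 in 2 of 20 simulations without change in the proximal share and in 20 of 20 with 8-fold higher odds.

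Segments were named by a rule fixed before the data were examined. It took IGHV5-2, IGHV2-2, IGHV1-26, IGHV1-72, IGHV11-2 and IGHV12-3, the 10 segments with the highest mean share over control libraries, and up to 10 segments per direction with the largest limma fold at adjusted p under 0.05. It also took every DH segment with at least 1% of DH calls in control libraries and every VH family. IGHV5-4 and IGHV2-3 were named after their values were seen. The alternatives tried were collapsing identical junctions, pooling reads, leaving out small libraries, nonproductive reads, stricter VH and DH calls, other normalizations and tests for segments, a replicate block, and leaving out each library. A test for count tables was planned only for a column of counts and was not run. Restricting to reads with a single VH gene would have removed no read and was not run. Tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.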

Results

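The libraries describe V(D)J junctions of Igh in pro-B cells, the stage at which VH segments are joined to an assembled DJH. Cells with floxed Cfp1 and Mb1-Cre (knockout) were compared with cells with floxed Cfp1 alone (control). CFP1 is a CpG-binding subunit of the SET1 complexes, which methylate histone H3 lysine 4. There were 3 control and 3 knockout libraries with the JH1 bait, and 2 control and 3 knockout libraries with the JH4 bait. The series title places the study among the roles of CFP1 in early B-lineage fate. The comparison asked how the Igh repertoire of pro-B cells differed between these 2 genotypes. No library carried Mb1-Cre without floxed Cfp1, so an effect of Mb1-Cre itself cannot be told apart from loss of CFP1. The files held 92182 reads, which reduced to 20993 distinct junctions when counted within each library.

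Knockout libraries held far fewer VDJ junctions than control libraries at both baits. JH1 control libraries had 18064, 17190 and 23474 reads, and JH1 knockout libraries had 67, 962 and 764. JH4 control libraries had 24086 and 7232 reads, and JH4 knockout libraries had 218, 67 and 58. On the log2 scale the read number fell by 6.42 (mean over baits), with every knockout library below every control library of its bait (exact permutation p = 0.005, the smallest possible, adjusted p = 0.00857). The count of distinct junctions was 3333 ± 2116 (SD, n = 3) in JH1 control and 71.3 ± 56.5 (SD, n = 3) in JH1 knockout libraries, and 5359 ± 4786 (SD, n = 2) against 21.0 ± 8.72 (SD, n = 3) at JH4. The amount of DNA per library was not held constant, so these numbers are yields of the libraries and not rates per cell.

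**Figure D1:**
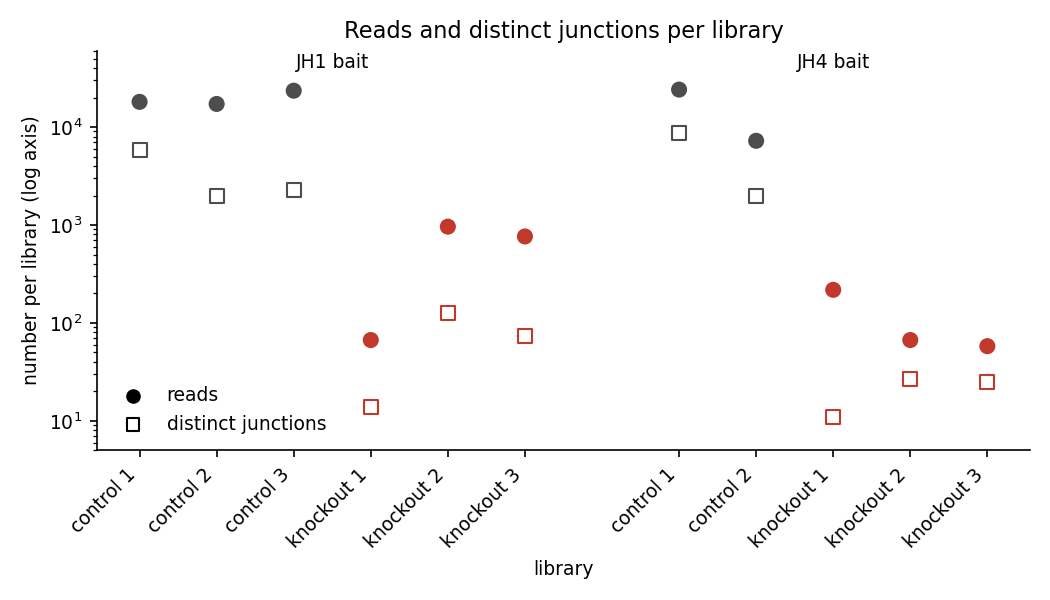
Number of reads (filled circles) and of distinct junctions (open squares) in each library on a log axis, with control libraries in grey and knockout libraries in red. Control libraries held 7232 to 24086 reads and knockout libraries 58 to 962.

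As a share of reads, usage of VH segments shifted from the distal and middle families to the families nearest to DH. In number, distinct proximal junctions were also fewer in knockout libraries. They were 746, 299 and 318 in JH1 control and 5, 100 and 60 in JH1 knockout libraries. At JH4 they were 1364 and 342 against 6, 20 and 22. Proximal families (IGHV5 and IGHV2) made up 14.1% ± 0.680 (SD, n = 3) of reads in JH1 control and 87.3% ± 5.86 (SD, n = 3) in JH1 knockout libraries. At JH4 they made up 15.98% ± 0.0461 (SD, n = 2) and 76.3% ± 14.7 (SD, n = 3). Distal families (IGHV1 and IGHV8) fell from 60.8% ± 1.54 to 8.28% ± 4.31 (SD, n = 3 each) at JH1 and from 58.6% ± 0.191 (SD, n = 2) to 18.2% ± 12.8 (SD, n = 3) at JH4. Middle families fell from 23.98% ± 1.83 to 4.00% ± 3.12 (SD, n = 3 each) at JH1 and from 24.7% ± 0.143 (SD, n = 2) to 5.51% ± 3.002 (SD, n = 3) at JH4.

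Each of these 3 differences separated all knockout from all control libraries of the same bait. The mean differences over baits were 66.7 percentage points for proximal, -46.5 for distal and -19.6 for middle families (exact permutation p = 0.005 for each, adjusted p = 0.00857). In nonproductive reads alone the proximal difference was 45.8 points (exact permutation p = 0.025) and the distal difference -37.9 points (exact permutation p = 0.005). The middle difference there was -7.03 points and did not pass (exact permutation p = 0.745). With distinct junctions counted once, proximal families made up 65.5% ± 25.9 of JH1 knockout and 72.2% ± 16.8 of JH4 knockout junctions (SD, n = 3 each), and the lowest library was JH1 knockout replicate 1 at 35.7%. Within a bait the 2-sided exact p was 0.1 for each, the smallest the design allows. The difference in proximal share was not shown to differ between baits (12.8 points apart, exact permutation p = 0.205). Within the first sequencing run the JH4 difference in proximal share was 54.2 points between 1 knockout and 1 control library. Within the second run it was 63.4 points between 2 knockout and 1 control library, and the JH1 libraries were all of the first run. The smallest libraries had wide counting intervals. Proximal reads were 58 of 67 in JH1 knockout replicate 1 (86.6%, 95% exact interval 76.0 to 93.7%) and 44 of 67 in JH4 knockout replicate 2 (65.7%, 53.1 to 76.8%). Those intervals treat reads as independent and are too narrow. Over distinct junctions the proximal shares of these libraries were 35.7% of 14 and 74.1% of 27.

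**Figure D2:**
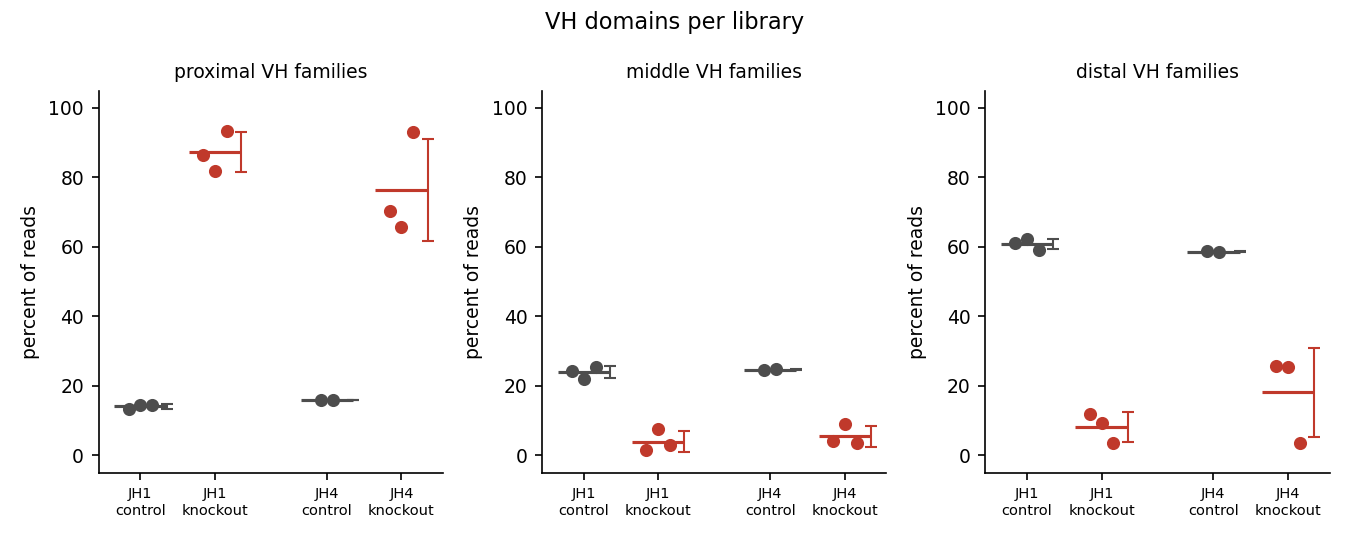
Percent of reads with a proximal, middle or distal VH family, with a point per library, horizontal lines at group means and bars of 1 SD (n = 3, 3, 2 and 3 from left to right in each panel). Knockout libraries lie between 65.7 and 93.5% for proximal families and control libraries between 13.4 and 16.01%.

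By family, 13 of 16 differed at adjusted p under 0.05, with 2 higher and 11 lower in knockout libraries. For rare families the test cannot tell lower usage from low depth, since all knockout libraries together held 277 distinct junctions. Control shares were 1.02% for IGHV11, 1.06% for IGHV12 and 0.895% for IGHV15 (means of 5 libraries). Families were not compared with thinned controls. IGHV5 rose from 8.71% ± 0.848 to 57.3% ± 9.56 (SD, n = 3 each) at JH1 and from 10.3% ± 1.02 (SD, n = 2) to 56.8% ± 2.52 (SD, n = 3) at JH4 (exact permutation p = 0.005, adjusted p = 0.00889). In nonproductive reads alone the IGHV5 difference was 21.8 points and did not pass (exact permutation p = 0.175). IGHV2 rose from 5.43% ± 0.474 to 30.0% ± 6.80 (SD, n = 3 each) at JH1 (both baits, exact permutation p = 0.015, adjusted p = 0.02). At JH4 its shares were 5.65% ± 0.976 (SD, n = 2) and 19.5% ± 16.5 (SD, n = 3), and 1 knockout library lay within the control range. Without JH4 control replicate 1 or 2 the IGHV2 difference of 19.6 or 18.9 points no longer passed (exact permutation p = 0.0625 and 0.075), and in nonproductive reads it was 23.99 points (exact permutation p = 0.075). The distal family IGHV1 fell by 40.7 points and IGHV8 fell by 5.82 points (exact permutation p = 0.005 and adjusted p = 0.00889 for each). IGHV6, IGHV7 and IGHV11 had 0 of 2136 knockout reads, which allows a share of up to 0.140% (0.256% without JH1 knockout replicate 2), against 2328, 2023 and 949 control reads. These reads were copies of 277 distinct junctions, over which the allowed share is wider. For IGHV11-2, of the IGHV11 family, the fold limit over distinct junctions was 0.562, so no drop is shown there. IGHV14 fell by 3.17 points and IGHV15 fell by 0.844 points, with 1 knockout read each (exact permutation p = 0.005 and adjusted p = 0.00889 for both). IGHV9 fell by 2.60 points (adjusted p = 0.00889 from the exact permutation test), IGHV3 fell by 3.99 and IGHV12 fell by 0.939 (adjusted p = 0.0145 for both), and IGHV10 fell by 2.30 (adjusted p = 0.0431). With identical junctions collapsed, IGHV3 and IGHV9 no longer passed (exact permutation p = 0.77 and 0.22), and in nonproductive reads IGHV3 turned to 7.42 points higher (exact permutation p = 1). The IGHV10 difference was -2.24 to -1.90 points, with exact permutation p of 0.05 to 0.0625, without any 1 of JH1 control replicates 1 and 3, JH4 control replicate 2 and JH4 knockout replicates 1 and 2. It also did not pass in nonproductive reads (-1.58 points, exact permutation p = 0.115) or without both knockout replicate 1 libraries (-1.93 points, exact permutation p = 0.0833). The IGHV12 family difference did not pass with reads pooled within groups (-0.802 points, exact permutation p = 0.065), and was -0.870 points without both knockout replicate 1 libraries and also without the libraries under 100 reads (exact permutation p = 0.0667 each). IGHV4, IGHV13 and IGHV16 did not pass, with exact permutation p of 0.72, 0.865 and 1. Without JH4 knockout replicate 2 IGHV13 fell by 1.11 points (exact permutation p = 0.0167), and by as much without the libraries under 100 reads (exact permutation p = 0.0333).

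IGHV5-2, also called VH81X and a frequently used DH-proximal segment, took the largest share of knockout reads. It made up 1.96% ± 0.397 of JH1 control and 41.0% ± 21.1 of JH1 knockout reads (SD, n = 3 each), and 2.79% ± 0.333 (SD, n = 2) against 35.4% ± 11.4 (SD, n = 3) at JH4. The mean difference was 35.8 points (exact permutation p = 0.005, adjusted p = 0.00857), and in nonproductive reads alone it was 17.7 points (exact permutation p = 0.095). In JH1 knockout replicate 1 a single junction supplied 40 of the 67 reads. With distinct junctions counted once, IGHV5-2 was 27.8% ± 0.636 of JH1 knockout and 34.4% ± 15.1 of JH4 knockout junctions (SD, n = 3 each), against 1.95% ± 0.335 (SD, n = 3) and 2.60% ± 0.264 (SD, n = 2) in controls. Without junctions also found in another library the JH1 knockout share was 45.8% ± 25.4 (SD, n = 3), with 4 junctions left in replicate 1. IGHV2-2 rose from 2.15% ± 0.389 (SD, n = 5) of control to 16.8% ± 6.71 (SD, n = 6) of knockout reads and IGHV5-4 from 1.60% ± 0.280 (SD, n = 5) to 16.08% ± 10.9 (SD, n = 6). IGHV2-3 rose from 1.13% ± 0.451 (SD, n = 5) to 5.86% ± 7.20 (SD, n = 6). IGHV5-2, IGHV2-2, IGHV5-4 and IGHV2-3 passed in the quasi-binomial fit of reads (adjusted p = 0.000106, 0.000106, 6.51e-05 and 0.0158) and in that of distinct junctions (1.40e-05, 0.000260, 0.000530 and 0.0378). In limma their log2 fold changes were 3.77 (adjusted p = 1.07e-13), 3.11 (6.40e-09), 2.92 (3.42e-06) and 0.98 (0.236). The IGHV2-3 reads came from 3 of 6 knockout libraries, and its limma fold was 1.86 (adjusted p = 0.00926) without JH1 knockout replicate 1 and 1.87 (adjusted p = 0.0327) without JH4 knockout replicate 1. In nonproductive reads alone IGHV5-2, IGHV2-2 and IGHV5-4 no longer passed in limma (log2 fold change 1.96, 2.28 and 2.20, adjusted p = 0.0648, 0.0502 and 0.0509). Without weights on log2(percent + 0.1) the IGHV2-3 fold turned to -0.01. IGHV5-4 did not pass in limma without weights (log2 fold change 2.01, adjusted p = 0.18) or with quantile normalization (1.85, adjusted p = 0.152).

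Among 129 segments with at least 10 reads, the quasi-binomial fit called 5 higher and 28 lower in knockout libraries. Its lower calls are uncertain, since in the simulations with changed segments 1.5 of 4.35 lower calls were right on average. Of 20 proximal segments tested, 4 were higher, 1 was lower and 15 did not pass (4 higher and 2 lower adjusted over the list alone). Of 32 middle segments, 9 were lower and 23 did not pass (10 lower adjusted over the list alone). Of 75 distal segments, 17 were lower and 58 did not pass (17 lower adjusted over the list alone). The fifth segment called higher, IGHV16-1, had 12 reads of 2 junctions in JH1 knockout replicate 2 and 0 reads elsewhere. With distinct junctions counted once, 4 of 113 segments were higher and 0 lower, with 21 at an unadjusted p under 0.05. The limma fit called 27 segments higher and 34 lower, and 23 segments were called by both fits in the same direction. Of its 27 higher segments, 23 had no knockout read, so they are not counted as higher here. In nonproductive reads alone limma called 1 segment. By list, limma called 8 proximal segments higher (5 with no knockout read) and 2 lower, 2 middle segments higher (both with no knockout read) and 10 lower, and 16 distal segments higher (all with no knockout read) and 22 lower. Adjusted over the list alone, these were 8 and 2, 2 and 9, and 16 and 23. Of its 10 largest fitted rises, 9 were such segments (IGHV1-8, IGHV1-17, IGHV1-21, IGHV1-32, IGHV1-43, IGHV1-73, IGHV2-7, IGHV6-4 and IGHV6-7), with at most 0.0314% of control reads each.

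Several distal and middle segments with control shares above 1% were rare or unseen in knockout libraries. IGHV1-72 made up 2.99% ± 0.287 (SD, n = 5) of control and 0.266% ± 0.602 (SD, n = 6) of knockout reads (quasi-binomial adjusted p = 0.00729, limma adjusted p = 0.000227). IGHV8-8 made up 2.69% ± 0.276 (SD, n = 5) and 0.0391% ± 0.0612 (SD, n = 6), and IGHV1-81 2.88% ± 0.611 (SD, n = 5) and 0.0218% ± 0.0534 (SD, n = 6), with quasi-binomial adjusted p of 0.00245 and 0.0432 and limma adjusted p of 0.000610 and 0.000227. IGHV1-55, IGHV3-6, IGHV8-12 and IGHV1-53 had 0 of 2136 knockout reads. Against the 3 reads that such a count allows over all knockout libraries, they were at least 18.5-fold, 17.4-fold, 12.5-fold and 12.2-fold lower (quasi-binomial adjusted p = 0.00346, 0.00245, 0.00222 and 0.00108). Without JH1 knockout replicate 2, which holds 962 of these reads, the limits were 10.2-fold, 9.56-fold, 6.89-fold and 6.69-fold, without JH1 knockout replicate 3 they were 11.9-fold, 11.2-fold, 8.05-fold and 7.82-fold, and over distinct junctions 2.36-fold, 2.23-fold, 1.73-fold and 1.48-fold. IGHV1-64 was also at 0, at least 19.2-fold lower (10.5-fold and 12.3-fold without those libraries, 2.45-fold over distinct junctions), and IGHV1-26 and IGHV1-9 had 1 knockout read each. Those 3 passed in limma (adjusted p = 0.000227, 0.000176 and 0.00141) and not in the quasi-binomial fit (0.0995, 0.0913 and 0.0864). None of the segments from IGHV1-72 to IGHV1-9 passed in the quasi-binomial fit of distinct junctions. Its adjusted p ran from 0.103 (IGHV1-55) to 0.498 (IGHV1-9), with 0.256 for IGHV1-72, 0.244 for IGHV8-8 and 0.327 for IGHV1-81. IGHV1-18, the segment with the highest control share, made up 3.52% ± 0.523 (SD, n = 5) of control and 2.93% ± 4.59 (SD, n = 6) of knockout reads. Its limma fold passed (log2 fold change -2.28, adjusted p = 0.00347) and its quasi-binomial fit did not (adjusted p = 0.229). With identical junctions collapsed the IGHV1-18 limma fold turned to 0.58 (adjusted p = 0.281). IGHV11-2 had 0 knockout reads and IGHV12-3 had 7 reads of 1 junction, and neither passed in limma (adjusted p = 0.0799 and 0.211). The IGHV11-2 limma fold turned from -1.66 to 1.19 with identical junctions collapsed (adjusted p = 0.0457), where it still had 0 knockout reads. The IGHV12-3 fold turned from -1.14 to 0.81 (adjusted p = 0.167).

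Within JH1 limma called 4 segments higher and 11 lower of 124, and the quasi-binomial fit 3 higher and 0 lower. Without JH1 knockout replicate 1, 2 or 3 the limma count was 3, 2 and 3. Within JH4 limma called 19 higher and 2 lower of 116, and the quasi-binomial fit called 0, with 15 at an unadjusted p under 0.05. The JH4 limma count was 0 without either control library and 1, 2 and 3 without knockout replicate 1, 2 and 3.

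**Figure D3:**
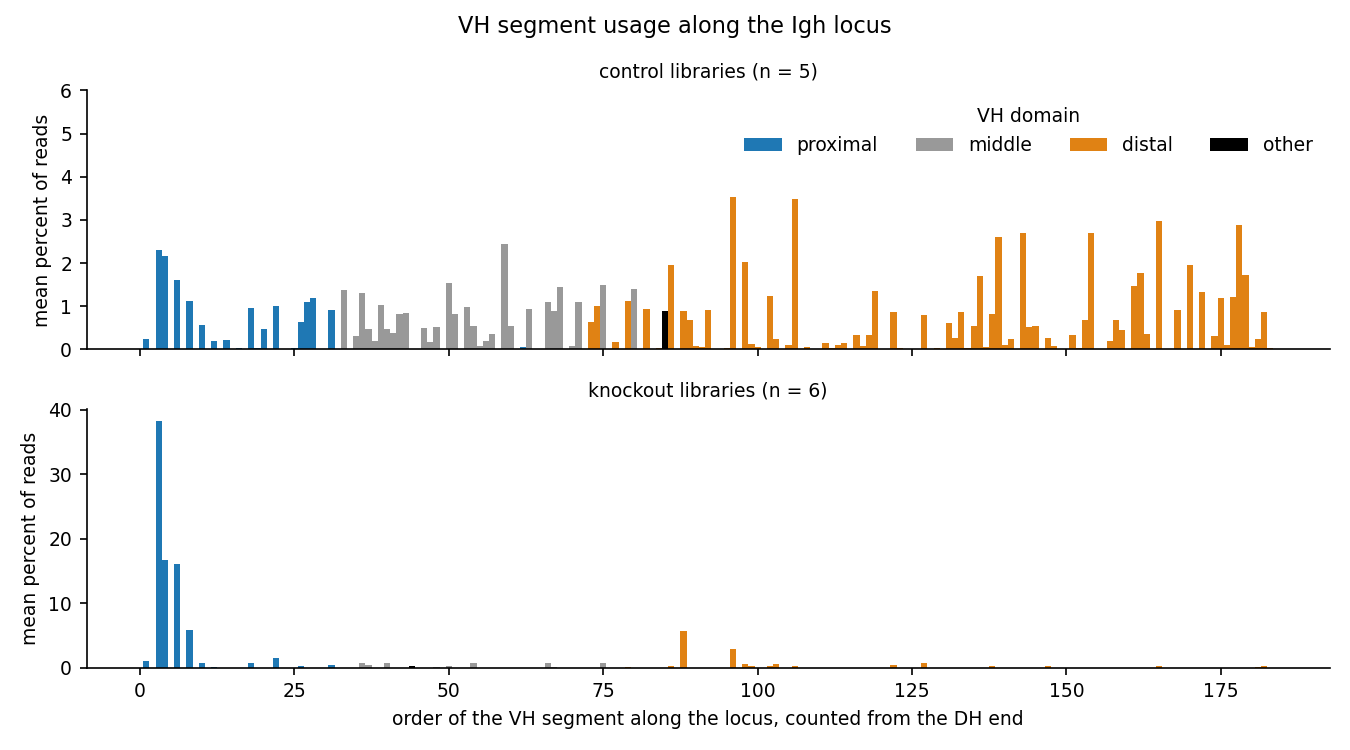
Mean percent of reads for each VH segment in the order of the genes along the locus, counted from the DH end, in 5 control libraries (top) and 6 knockout libraries (bottom, on a larger scale). Proximal segments are blue, middle segments grey and distal segments orange. The knockout bars at the DH end reach 38.2% for IGHV5-2, which is at 2.30% in controls.

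Among DH segments, DFL16.1 (IGHD1-1), at the VH side of the DH cluster, was less used in knockout libraries. Reads without a DH call, which all DH shares leave out, were 7.55 to 12.5% in control libraries. In knockout replicates 1, 2 and 3 they were 61.2, 14.6 and 21.5% at JH1 and 31.7, 5.97 and 12.1% at JH4. Of reads with a DH call DFL16.1 made up 57.0% ± 3.16 in JH1 control and 19.7% ± 6.95 in JH1 knockout libraries (SD, n = 3 each), and 32.7% ± 1.74 (SD, n = 2) against 10.3% ± 7.82 (SD, n = 3) at JH4. The mean difference was -29.9 points (exact permutation p = 0.005). Adjusted over the 12 measures p was 0.00857, and over the 12 DH segments it was 0.06, which did not pass. The JH4 difference was -25.9 points in the first sequencing run and -20.02 in the second. Over distinct junctions it was 15.9 points higher in the first run, where the knockout library had 8 junctions with a DH call, and -21.8 in the second (JH4 alone, exact permutation p = 0.6). With identical junctions collapsed the difference was -18.2 points (exact permutation p = 0.075), and with reads matching a single DH gene -25.6 points (exact permutation p = 0.085). In nonproductive reads alone it was -16.7 points (exact permutation p = 0.33). DQ52 (IGHD4-1), the DH nearest to JH, made up 4.28% ± 0.864 and 1.93% ± 1.86 (SD, n = 3 each) at JH1 and 4.63% ± 0.0502 (SD, n = 2) and 4.08% ± 3.54 (SD, n = 3) at JH4 (exact permutation p = 0.335). With reads pooled within groups the DQ52 difference was -2.62 points (exact permutation p = 0.015). With identical junctions collapsed, or with reads matching a single DH gene, it turned to 0.345 or 2.39 points (exact permutation p = 0.88 and 0.59). IGHD2 segments together made up 33.1% ± 3.31 and 70.8% ± 5.57 (SD, n = 3 each) at JH1 and 49.1% ± 0.0106 (SD, n = 2) and 71.8% ± 16.5 (SD, n = 3) at JH4, a sum formed after the values were seen (exact permutation p = 0.01). With reads matching a single DH gene the exact permutation p of that sum was 0.205, and in nonproductive reads 0.25. IGHD3-2 fell by 2.32 points and IGHD1-2 fell by 1.25 before adjustment (exact permutation p = 0.01 and 0.02, adjusted p = 0.06 and 0.08). IGHD2-1, 2-2, 2-3, 2-4, 2-5, 2-10, 2-12 and 3-3 did not pass (exact permutation p of 0.05 to 0.99).

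The productive share varied widely among knockout libraries. Control libraries had 71.5% ± 3.54 (SD, n = 3) productive reads at JH1 and 68.3% ± 0.299 (SD, n = 2) at JH4. Knockout replicates 2 and 3 had 15.7% and 18.5% at JH1 and 13.4% and 19.0% at JH4. Knockout replicate 1 had 70.1% (95% exact interval 57.7 to 80.7%) at JH1 and 94.5% (90.6 to 97.1%) at JH4. Those intervals treat reads as independent and are too narrow. Over distinct junctions the shares were 57.1% of 14 at JH1 and 72.7% of 11 at JH4. In these libraries the most frequent junction held 59.7% and 30.7% of reads. The mean difference of -31.3 points did not pass (exact permutation p = 0.085, adjusted p = 0.102). Without JH4 knockout replicate 1 it was -44.4 points (exact permutation p = 0.0333). In the first sequencing run alone it was -5.14 points, and without the libraries under 100 reads -14.1 points. Over distinct junctions the productive share was 70.1% ± 3.58 and 35.4% ± 19.7 (SD, n = 3 each) at JH1 and 67.6% ± 0.0176 (SD, n = 2) and 34.6% ± 33.3 (SD, n = 3) at JH4 (exact permutation p = 0.035). Between libraries of the first run the JH4 difference in reads was 26.4 points, and in the second run it was -52.3.

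**Figure D4:**
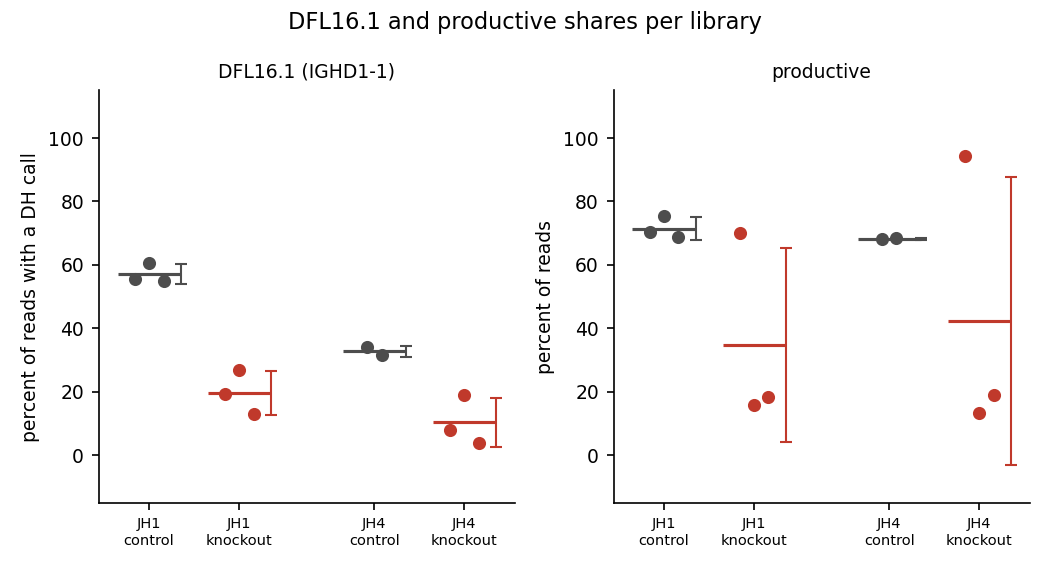
DFL16.1 as percent of reads with a DH call (left) and productive reads as percent of all reads (right), with a point per library, lines at group means and bars of 1 SD (n = 3, 3, 2 and 3 from left to right). DFL16.1 lies between 31.5 and 60.7% in control and between 3.92 and 26.9% in knockout libraries, and the knockout points at 70.1% and 94.5% productive are both replicate 1.

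CDR3 length over in-frame reads was 33.5 ± 0.215 and 28.4 ± 6.25 nucleotides (SD, n = 3 each) at JH1 and 32.2 ± 0.739 (SD, n = 2) and 28.6 ± 2.76 (SD, n = 3) at JH4 (exact permutation p = 0.065). The mean difference was -4.35 nucleotides. It was -6.03 without JH1 knockout replicate 2 (exact permutation p = 0.01) and -1.92 with identical junctions collapsed (exact permutation p = 0.06). N nucleotides between VH and DH averaged 4.24 ± 0.0388 and 4.65 ± 1.83 (SD, n = 3 each) at JH1 and 4.10 ± 0.196 (SD, n = 2) and 3.88 ± 0.714 (SD, n = 3) at JH4 (exact permutation p = 0.945). The mean difference of 0.0925 turned to -0.482 with reads pooled within groups (exact permutation p = 0.01), and it was -0.419 without JH1 knockout replicate 1 and -0.114 without JH4 knockout replicate 3. Between DH and JH they averaged 2.64 ± 0.164 and 2.98 ± 0.152 (SD, n = 3 each) at JH1 and 3.64 ± 0.0686 (SD, n = 2) and 5.42 ± 0.650 (SD, n = 3) at JH4, a mean difference of 1.06 (exact permutation p = 0.005, adjusted p = 0.00857). With identical junctions collapsed that difference was 1.23 and no longer passed (exact permutation p = 0.195), with the JH1 difference turned to -0.274 and the JH4 difference at 2.73.

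Repeats of the same junction were compared in the 8 libraries with at least 100 reads. In 100 drawn reads, 96.9% ± 1.68 (SD, n = 3) were distinct in JH1 control and 50.2% ± 11.9 (SD, n = 2) in JH1 knockout libraries, and 98.0% ± 1.81 (SD, n = 2) against 7.94% in the only JH4 knockout library with enough reads (exact permutation p = 0.0333, the smallest for these 8 libraries, adjusted p = 0.05, which is not under the threshold). Without JH4 knockout replicate 1 only JH1 remained, with a difference of -46.7 points (exact permutation p = 0.1). JH1 knockout replicates 2 and 3 and JH4 knockout replicate 1 held 127, 73 and 11 distinct junctions in all. Their shares were thus limited by the low yield of junctions and are not a separate result.

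VH usage was not shown to differ between baits in control libraries. Of 128 segments tested with limma between the 3 JH1 and 2 JH4 control libraries, 0 passed at adjusted p under 0.05 and 2 had an unadjusted p under 0.05. The quasi-binomial fit called 0, with 3 at an unadjusted p under 0.05. Without JH1 control replicate 2 limma called 1 segment.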

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

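Among DH segments, IGHD2-10 and IGHD3-3 differed between baits in their genotype difference. For IGHD2-10 the JH4 difference minus the JH1 difference was -3.11 percentage points, and for IGHD3-3 it was -5.39 (exact permutation p = 0.02 each). In both cases the JH4 knockout libraries held 0 reads of the segment and JH1 knockout replicate 3 held the highest share. Of 41 such differences tested, 2 had p under 0.05 where chance gives 2.05, so this number is no more than chance gives.

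JH4 knockout replicate 2 held reads with another JH segment than its bait's. They were 5.97% of its reads (4 of 67), against at most 0.152% in a control library. These reads are few, and the domain comparisons restricted to reads with the bait's own JH kept their direction and stayed past the threshold, with a proximal difference of 66.4 points. No explanation of these reads was tested.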

How the results depend on the processing

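Alternatives chosen after the results were seen were leaving out both knockout replicate 1 libraries, the first sequencing run alone, reads with the bait's own JH, junctions found in another library, quasi-binomial regression on collapsed junctions and segments with a mean share of at least 2%. For the 16 results that answer a comparison, 220 alternatives, counting both planned ones and those chosen afterwards, kept direction and side of the threshold, or for counts of segments stayed within 1.5 times. Those that did not are printed below. Among single families, DH segments and VH segments 921 did so, 126 fell short of the threshold, 21 newly passed and 40 turned direction. Most of those that turned had not passed before or after.

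Smaller designs gave fewer arrangements, which alone ends a call at 0.05. Within a bait, correlations between knockout and control libraries were -0.0469 to 0.0997 with the same number and -0.132 to 0.132 with different numbers. At JH4 the 2 control libraries gave each knockout library values of equal size and opposite sign, as deviations from their mean do. The values are thus not correlations of VH usage itself. At JH1 the same-number control gave the highest value for each knockout library, and at JH4 the order was mixed. These low values do not settle whether numbers pair libraries. They compare no JH1 with a JH4 library, so a shared animal stays possible. Pairing is tested only here. With same-numbered libraries averaged over baits (smallest exact p 0.1) the differences were -6.56 for log2 reads, -46.6 distal, 66.99 proximal, -19.7 middle, 35.9 IGHV5-2, -33.6 DFL16.1 and 1.21 N nucleotides DJ. As a replicate block (smallest exact p 0.0625) they were -6.25, -42.8, 62.5, -19.1, 33.05, -28.3 and 1.23, with N nucleotides VD turned to -0.114, IGHV4 to 0.0241, IGHV13 to 0.0106 and IGHD2-12 to -0.409, and the limma counts were 55 over both baits, 5 at JH4 and 1 for the bait effect in controls. With the first sequencing run only (smallest exact p 0.05) they were -42.8 distal, 63.7 proximal, -20.2 middle, 30.2 IGHV5-2, -31.6 DFL16.1 and 1.05 N nucleotides DJ, and, turned, -0.186 N nucleotides VD, -0.725 IGHD2-12 and -0.751 IGHD2-5.

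Other settings changed calls, and the cause was not tested. Nonproductive reads only gave -7.03 middle, 17.7 IGHV5-2, -16.7 DFL16.1 and, turned, 7.42 for the IGHV3 family, 0.0705 IGHD2-10, -0.379 IGHD2-12 and -0.945 IGHD2-4. Identical junctions collapsed gave -18.2 DFL16.1, -33.9 productive share (now passing) and 1.23 N nucleotides DJ and, turned, 0.345 DQ52 and -0.839 IGHD3-3. Reads with a single DH gene gave -25.6 DFL16.1 and, turned, 2.39 DQ52 and -0.361 IGHD2-12. Reads pooled within group gave -2.62 DQ52 and -3.22 CDR3 length (both now passing) and, turned, -0.482 N nucleotides VD and -0.734 IGHD2-12. Junctions found in another library left out turned IGHD2-12 to -0.543. Libraries under 100 reads left out gave -3.965 DQ52 (now passing) and, turned, -0.628 N nucleotides VD, -1.40 IGHD2-12 and -0.888 IGHD2-2. Both knockout replicate 1 libraries left out gave -53.2 productive share (now passing) and, turned, -0.314 N nucleotides VD, 0.375 IGHV4, 0.0106 IGHV13, 0.354 IGHD2-1 and -0.0215 IGHD2-12.

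Leaving out 1 library at a time gave -44.4 to -24.1 for productive share (lowest without JH4 knockout replicate 1) and -6.03 to -2.94 for CDR3 length (lowest without JH1 knockout replicate 2). The distinct junction share ranged from -72.6 to -46.7, with 10 to 20 arrangements, and 500 reads drawn gave -68.9 (exact p 0.1). IGHD3-3 ranged from -1.31 to 1.69 and turned without JH1 knockout replicate 3. N nucleotides VD ranged from -0.419 to 0.461 and IGHD2-12 from -0.4805 to 0.5715, both turning without JH1 knockout replicate 1 or JH4 knockout replicate 3. IGHV4 ranged from -1.095 to 0.0241, turning without JH1 knockout replicate 1 or JH4 knockout replicate 1 or 3, and IGHV13 from -1.109 to 0.0106, turning without JH4 knockout replicate 1 or 3.

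The number of VH segments called in limma moved with both the method and the choice of reads. Over both baits (61) it was 92 without weights on log2(percent + 0.1), 33 by quasi-binomial regression, 1 in nonproductive reads, 4 by quasi-binomial regression on collapsed junctions, 3 among segments with a mean share of at least 2%, and 40 with both knockout replicate 1 libraries left out. The 92 were 2 higher and 90 lower, and collapsed junctions gave 63 higher and 1 lower. At JH1 (15) it was 75 without weights, 3 by quasi-binomial regression, 30 with every segment, 2 in nonproductive reads and 2 to 22 without 1 library. At JH4 (21) it was 89 without weights, 0 by quasi-binomial regression (15 at an unadjusted p under 0.05), 68 with quantile normalization, 48 with every segment, 73 with identical junctions collapsed and 0 to 3 without 1 library. For the bait effect in controls it was 0 to 1 without 1 library. In 20 simulations without change, limma called 20.35 segments higher on average and the fit without weights 49.45 lower.

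Named segments turned in 2 settings. Without weights on log2(percent + 0.1) the log2 folds were -0.20 IGHV1-17, -0.17 IGHV1-21, -0.25 IGHV1-32, -0.24 IGHV1-43, -0.14 IGHV1-73, -0.25 IGHV1-8, -0.26 IGHV2-7, -0.21 IGHV6-4 and -0.20 IGHV6-7, all with 0 knockout reads, where limma gave 4.34 to 5.02, and -0.0115 for IGHV2-3. With identical junctions collapsed IGHV1-18 turned to 0.58, with 8 knockout junctions, IGHV12-3 to 0.81, with 1, and IGHV11-2 to 1.19, with 0.

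A count-model alternative and a filter for reads with a single VH gene were not run, since no column holds counts and the filter removes no read. Quasi-binomial folds that diverged at a count of 0 were left out.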

Other observations

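Of the tests in this part, the other splits of the libraries and the DFL16.1 share among proximal junctions were set before their results were seen. Leaving out junctions found in another library was added after other results were seen, with its bound for the productive share written before that value. The others were chosen afterwards.

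The higher proximal share of knockout libraries was weighed against 3 technical explanations. PCR copies of a few junctions are argued against by distinct junctions, whose proximal share was 53.6 points higher (exact permutation p = 0.005). Chance sampling of few junctions is argued against by control libraries thinned to the same number of junctions, since 5 of 6 knockout libraries lay above the central 95% of such draws. JH1 knockout replicate 1 did not, with 35.7% of 14 junctions. The sequencing run is argued against by the JH1 libraries of 1 run, which differed by 73.1 points. An effect of CFP1 loss on VH choice stays a hypothesis, found and tested in the same libraries, and yield per cell was not measured. The design cannot tell it apart from an effect of Mb1-Cre itself.

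JH1 knockout replicate 1 held 8 distal junctions with 1 read each, and all of them, 100%, also occurred in a JH1 control library of the same run. Distal junctions drawn from controls were shared in 0.113% on average. Reads carried over from control libraries are a candidate explanation, and cells that kept CFP1 are argued against, since their junctions would be their own. In JH1 knockout replicate 3, 7 of 9 distal junctions were shared, in replicate 2 it was 4 of 14. JH4 knockout replicate 1, of the first run, shared 1 of 3, and the JH4 knockout libraries of the second run shared 0 of 5 and 0 of 2. The distal share of distinct junctions in JH1 knockout libraries was 26.8% ± 26.3 with shared junctions, replicate 1 being at 57.1%, and 3.87% ± 4.16 without them (SD, n = 3 each).

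The lower productive share was weighed against VH usage, copies and carried-over reads. Reweighting control junctions to knockout VH usage lowered their productive share from 69.9 to 47.7% at JH1 and from 67.6 to 37.5% at JH4. Pooled knockout shares were 25.5% and 25.4%, so gaps of 22.2 and 12.1 points remained. VH usage can thus account for part of the pooled drop at both baits. The reweighted share lay inside the exact interval of the knockout share at JH4 (15.3 to 37.9%) and above it at JH1 (19.6 to 31.6%). By library the gaps were 3.46, 26.9 and 17.7 points at JH1 and -35.5, 26.2 and 17.9 at JH4. Over this spread it cannot be told at either bait whether VH usage accounts for the whole drop. Copies are argued against by distinct junctions (-33.9 points, exact permutation p = 0.035). The difference without shared junctions (-31.1 points, exact permutation p = 0.095) decides nothing on carried-over reads, since reads from controls, 68.1 to 75.5% productive, would raise most knockout shares. A loss of cells with productive junctions, or their exit from the sorted stage, was not tested.

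Within the proximal families the change may depend on position. Over 12 IGHV5 and IGHV2 segments with at least 50 control junctions, the knockout to control ratio of distinct junctions, pooled over libraries, fell with order from the DH end (Spearman rho -0.832, permutation p = 0.001). In that order it was 13.7 for IGHV5-2, 7.34 for IGHV2-2, 8.88 for IGHV5-4, 7.18 for IGHV2-3 and 4.36 for IGHV5-6. Among the 7 farther segments it did not fall steadily, with 1.47 for IGHV5-12, 0 for IGHV5-9-1, 0.959 for IGHV2-9-1, 1.21 for IGHV5-15, 0.358 for IGHV5-16, 0.265 for IGHV5-17 and 1.17 for IGHV2-9, the farthest. Without the 2 farthest segments rho was -0.721, and without JH1 knockout replicate 2 it was -0.592 (permutation p = 0.047). The 6 junctions of IGHV5-6 came from 1 knockout library and those of IGHV2-3 from 3. Of these segments 8 had at most 6 knockout junctions each. The 4 segments with reads nearest to DH (up to IGHV5-4) made up 6.30% ± 1.17 (SD, n = 5) of control and 72.0% ± 9.07 (SD, n = 6) of knockout reads (exact permutation p = 0.005), a choice of segments made after their values were seen.

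The lower DFL16.1 share was also seen among junctions with a proximal VH. At JH1 it was 49.4% of 1230 control and 21.6% of 139 knockout junctions, and at JH4 29.8% of 1530 and 7.32% of 41. Over libraries the difference was -24.9 points (exact permutation p = 0.02), with 5 of 6 knockout libraries below the controls of their bait and JH4 knockout replicate 1 above them at 33.3% of 3 junctions. Of the 5 below, JH1 knockout replicate 1 also held only 3 such junctions, at 0%. With the smaller pooled drop at -22.5 points, these differences argue against the shift between VH domains as the whole cause. They cannot decide on VH usage as such, since usage within the proximal domain differed as well. IGHV5-2 held 83 of 213 proximal knockout junctions and 454 of 3069 proximal control junctions. Junctions with other VH domains were few in knockouts and did not all go this way. At JH4 the knockout share was 2 of 4 middle and 4 of 10 distal junctions, against 34.8% and 34.5% in controls, and at JH1 it was 7 of 13 middle and 9 of 27 distal junctions, against 56.1% and 57.9%.

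Knockout libraries also held fewer VH segments than their number of junctions gives in thinned controls. JH1 knockout replicates 2 and 3 held 32 and 21 segments, against medians of 62 and 46. JH1 knockout replicate 1, with 11 against 13, lay inside the thinned range of 10 to 14.

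For the limma count over both baits, 1 of 100 splits drawn from the 200 possible gave at least 61 segments, the real split included, and the highest other of those drawn gave 50. This argues against a chance split among those drawn. It says nothing against the offset effect seen in the simulations, since the groups differ in depth. Within JH1 the real split gave 15 and the highest other 0, and 10 splits are too few for a share under 0.05, since the real one is 1 of them.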
